A study of Mus musculus with 15 samples.

How the data were processed

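Epithelial cells were isolated from the prostates of C57BL/6 mice and profiled by RNA sequencing and by ATAC-seq, which reads the DNA that a transposase can reach and so maps open chromatin. Per the labels' protocols, tamoxifen was injected at 8 weeks of age, the prostate was digested to single cells 1 week later, and cells positive for both CD326 (EpCAM, an epithelial surface protein) and the fluorescent protein EYFP were sorted by flow cytometry. Samples were grouped by the genotype in their labels, EYFP, ETV4WT or ETV4AAA. RNA was measured in 9 libraries, 3 per genotype, and chromatin in 6 libraries, 2 per genotype. ATAC samples of a genotype are numbered in the labels, and each RNA sample has its own identifier in its title, which may be an animal number. No label states that each sample came from a separate animal, so p-values measure the spread between these samples.

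The RNA values are regularized log (rlog) values on a log2 scale, deposited by the authors as 1 table of 33785 entries, 33781 Ensembl genes and 4 added sequences named CreERT2, hETV4, IRES-nlsEGFP and Neo. The regularized log divides counts by a size factor per library and draws each gene towards its mean over the libraries, more strongly the fewer reads it has, so the changes of genes with few reads are understated. The submitters' processing notes name STAR 2.3, DESeq2 1.16.1, R 3.4.1 and the builds GRCm38.p6 and mm9, without roles. The counting tool, the annotation, the strand setting and any filter are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated. An rlog table keeps no depth, and the depth of the RNA libraries is unknown. Of 33781 Ensembl identifiers, 33708 were found in a table of mouse gene symbols, and 25 symbols that had been turned into dates were restored through their identifiers.

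The ATAC values were also deposited on a log2 scale, for 181279 regions shared by the 6 libraries, with a median width of 429 bases and a range from 150 to 3831. Undoing the logarithm and subtracting 1 gave, in each library, whole multiples of 1 step for 100% of values within 0.01 reads, so the deposited value is the log2 of 1 plus the read count divided by a size factor. The read counts recovered in this way sum to between 7495561 and 16688464 reads in regions per library. Bowtie2, MACS2, deepTools and HOMER stand in the submitters' processing notes without versions, and peak calling settings are not given in the sources used here. The last region of chromosome 1 ends at base 197193825, beyond the last gene of that chromosome in GRCm38.p6, at 195291439, so the coordinates were read as mm9.

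All tests used limma 3.58.1 in R 4.3.3: a linear model with a mean per genotype over all libraries of an assay, contrasts between genotypes, moderated variances with a trend on the mean level, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. RNA genes were kept with a mean rlog of at least 3, which left 15444 genes with 6 residual and 2.94 prior degrees of freedom. In ATAC, 1 region without variance was left out, and 181278 regions were tested with 3 residual and 14.66 prior degrees of freedom. The 28 gene lists were tested with limma's camera, which asks whether a list's genes changed more in a direction than other genes, with a preset correlation of 0.01 between genes, adjusted over lists. Camera with the estimated correlation between a list's genes was an alternative. The lists, the tests, the comparisons and most alternatives were fixed before the data were examined. The lists cover p53 targets, senescence, cell cycle, ERK output, the ETS family, prostate cell types (distal luminal, proximal luminal, basal and neuroendocrine), androgen receptor targets, epithelial to mesenchymal transition, matrix proteases, interferon, NF-kB, dissociation stress, unfolded protein response, sterol and fatty acid synthesis, oxidative phosphorylation, Wnt, Notch, leukocytes, fibroblasts and smooth muscle, endothelium, peripheral glia, seminal vesicle secretion, cytosolic ribosomal proteins, mitochondrially encoded genes and histones. Of the 47 measured members of the histone list, 21 are H2 genes of the major histocompatibility complex that its symbol pattern also took.

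Named genes follow a rule set before the data were examined: Etv4 and Trp53, then for each RNA comparison the 10 largest rises and the 10 largest falls among genes past the threshold without overlap between the libraries of both genotypes, leaving out predicted gene models, and for each list the 3 members with the smallest p. The added sequences, Epcam, the androgen receptor list members Pmepa1 and Camkk2, and the leukocyte list members Cd74, H2-Aa and H2-Ab1 are named outside this rule, chosen after their values were seen. For ATAC the rule takes the 5 largest rises and 5 largest falls without overlap.

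RNA libraries carry a library request letter in the labels. Request F holds 4 libraries, all of ETV4WT and replicate 1 of ETV4AAA, and request G holds 5, all of EYFP and replicates 2 and 3 of ETV4AAA. ETV4AAA was therefore also compared with EYFP within request G and with ETV4WT within request F, where it has 1 library that is assumed to vary like the others. ETV4WT and EYFP share no request letter, and a fit with the request as a covariate rests on 1 ETV4AAA library. All ATAC libraries carry 1 request. Further alternatives were no filter, a minimum mean rlog of 5, ATAC without the 45320 regions of lowest mean, quantile normalization, centring each library on its median, no variance trend, array weights, fits of the compared genotypes alone, leaving out each library, a minimum absolute log2 change of 1, and the replicate number as a block. A limma voom fit on the recovered ATAC reads and a fit after thinning them to 7495561 reads per library were added after seeing the data.

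The tests were tried on simulated data for ETV4AAA against EYFP, with 200 of the 15444 genes or 181278 regions changed. With noise drawn at the moderated standard deviation, changes of 1, 2 and 3 log2 units were recovered for 28.8%, 80.9% and 91.5% of genes, with 6 false calls, and for 25.4%, 75.3% and 93.3% of regions, with 19 false calls. With noise drawn at each feature's unmoderated standard deviation, the first setting tried, recovery was 31.5%, 72.6% and 88.7% of genes, with 5 false calls, and 1.8%, 17.7% and 54.3% of regions, with 0 false calls. In a simulation over 15444 genes with 1 shifted list among 28, that list was called, and 1 other list was too. Noise was drawn independently for each feature and library, without a request difference or a library standing apart. The 2660 genes and 92543 regions called in the data also exceed the 200 changed here. Recovery and false calls in the data may therefore differ. No pair of RNA libraries of a genotype held an identical value in any gene kept. Replicate 1 of ETV4AAA stood apart from its replicates 2 and 3, with r = 0.926 and 0.931 across genes and median absolute differences of 0.669 and 0.628, against r = 0.993 and 0.15 between replicates 2 and 3. Within EYFP and ETV4WT the r ranged from 0.981 to 0.989. In ATAC, replicate pairs differed by more than sampling noise, with a chi-square per region of 1.27 in EYFP, 1.49 in ETV4WT and 1.59 in ETV4AAA.

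Genes next to the regions and sequence motifs within them were not analysed here, because no genome or annotation of mm9 was used here. Where a region's reads are near 0, levels per library are given instead of a fold, beside the level that 3 reads would have. This level covers counting error only.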

Results

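Sorted prostate epithelial cells from mice of 3 genotypes were profiled by RNA sequencing and by ATAC-seq. The labels name the genotypes EYFP, ETV4WT and ETV4AAA, and the series title speaks of stabilized ETV4, an ETS family transcription factor, together with loss of p53 in prostate carcinoma. EYFP serves as the control here, and ETV4WT and ETV4AAA are read as a wild-type and an altered form of ETV4. The labels do not say which residues AAA replaces. There were 3 RNA libraries and 2 ATAC libraries per genotype. ATAC libraries held 9946906 and 7495561 reads in regions for EYFP, 15443902 and 16688464 for ETV4WT, and 11997291 and 13224819 for ETV4AAA. The depth of the RNA libraries is unknown. RNA changes are differences of rlog values in log2 units, over 3 libraries per genotype, with the standard error (SE) of the limma fit, and ± gives the standard deviation (SD, n = 3).

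The human ETV4 sequence in the table, hETV4, separated EYFP from both ETV4 genotypes. Its mean rlog was 9.06 ± 0.04 in EYFP, 13.48 ± 0.52 in ETV4WT and 14.02 ± 0.55 in ETV4AAA. Relative to EYFP it was higher by 4.95 (SE 0.31, adjusted p = 2.04e-05) in ETV4AAA and by 4.42 (SE 0.31, adjusted p = 0.000997) in ETV4WT, while the difference of 0.53 between the ETV4 genotypes did not pass (adjusted p = 0.224). Its change in ETV4AAA was 5.27 within request G, that in ETV4WT was 5.38 with the request as a covariate, and ETV4AAA minus ETV4WT was -0.11 within request F. Mouse Etv4 (ENSMUSG00000017724, chromosome 11, 101769747 to 101785310 in GRCm38.p6) was at 4.83 ± 0.63 in EYFP, 7.74 ± 0.52 in ETV4WT and 6.23 ± 0.46 in ETV4AAA. Its rise in ETV4AAA (1.40, SE 0.41, adjusted p = 0.0445) was called under 7 of 18 alternatives, with adjusted p up to 0.147, and its rise in ETV4WT (2.91, adjusted p = 0.019) under 11 of 17, with adjusted p up to 0.0966. Reads of the human and the mouse sequence may have been shared between these entries, which was not tested. The tumour suppressor gene Trp53 (ENSMUSG00000059552, chromosome 11, 69580348 to 69591873) was at 9.79 ± 0.05 in EYFP, 10.29 ± 0.20 in ETV4WT and 11.40 ± 0.44 in ETV4AAA. It rose in ETV4AAA by 1.61 (SE 0.22, adjusted p = 0.00129; 1.36 within library request G), and its difference of 0.50 in ETV4WT did not pass (adjusted p = 0.164, and -0.26 with the request as a covariate).

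Other sequences introduced into the mice, or tied to the locus used for that, also differed. The IRES-nlsEGFP entry, which has nearly the sequence of EYFP, was at 16.82 ± 0.03 in EYFP, 13.49 ± 0.30 in ETV4WT and 13.69 ± 0.31 in ETV4AAA. CreERT2, the tamoxifen-activated recombinase, was at 13.18 ± 0.08 in EYFP and fell by 0.62 in ETV4WT (adjusted p = 0.0263) and by 1.58 in ETV4AAA (adjusted p = 6.72e-05). Neo was at 11.12 ± 0.12, 10.59 ± 0.33 and 11.42 ± 0.18 in EYFP, ETV4WT and ETV4AAA. Gt(ROSA)26Sor, the noncoding transcript of the ROSA26 locus, was at 10.93 ± 0.03 in EYFP, 9.39 ± 0.09 in ETV4WT and 7.42 ± 0.27 in ETV4AAA. Epcam, which encodes the protein used for sorting, was at 14.37 ± 0.04 in EYFP and 12.18 ± 0.34 in ETV4WT, and at 12.84, 15.08 and 15.11 in the ETV4AAA replicates. It was thus lower in each of the 4 libraries of request F than in each of the 5 libraries of request G.

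**Figure D1:**
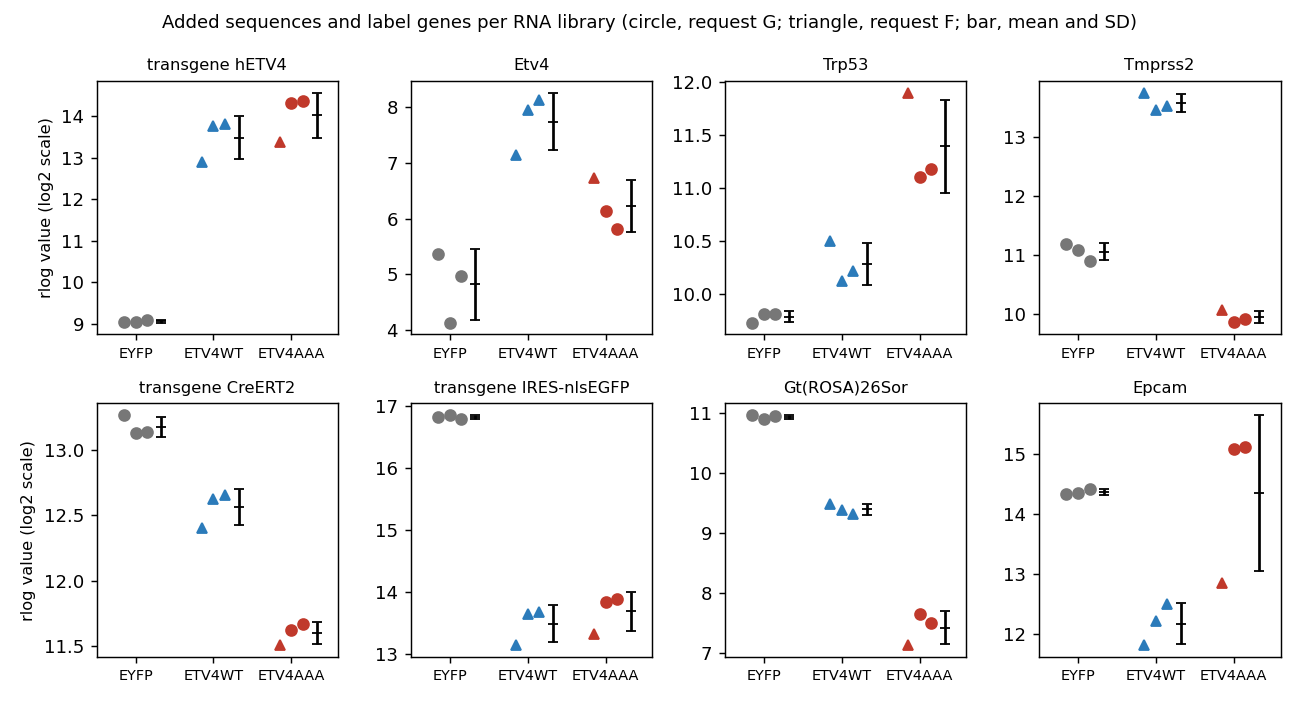
Rlog value (log2 scale) per RNA library of hETV4, Etv4, Trp53, Tmprss2, CreERT2, IRES-nlsEGFP, Gt(ROSA)26Sor and Epcam by genotype, with the mean and SD, circles for library request G and triangles for request F. hETV4 has a mean of 9.06 in EYFP and of 13.48 and 14.02 in ETV4WT and ETV4AAA, and Epcam is lower in every triangle than in every circle.

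The comparison of ETV4AAA with EYFP asks what the altered form does to the prostate epithelium. The largest rise was that of Pyy (ENSMUSG00000017311, chromosome 11, 102106676 to 102107832), the gene of the gut hormone peptide YY, from 9.60 ± 0.18 to 17.71 ± 1.41, a change of 8.11 (SE 0.56, adjusted p = 3.51e-05; 7.43 within request G). Flt4, the receptor of lymphatic endothelial growth factors, rose by 7.19 (SE 0.42, adjusted p = 1.71e-05; 6.84 within request G), and Dusp6, a phosphatase induced by ERK signalling that switches ERK off, rose from 11.35 ± 0.08 to 15.88 ± 0.17, by 4.53 (SE 0.15, adjusted p = 1.87e-06; 4.63 within request G). Rab3b, Vsig2, S100g, H19, Ctla2a, Bcan, Bcl6b and Adgrg3 rose by 6.76 to 7.86. S100g was at 17.11 in replicate 1 of ETV4AAA and at 12.09 and 11.82 in the others. The largest falls were those of C1s2, a complement protease gene, from 14.89 ± 0.04 to 11.13 ± 0.26, by 3.76 (SE 0.16, adjusted p = 4.2e-06; -3.65 within request G), and of Cuzd1 and Dsc1, by 3.56 and 3.53. In all, 1585 genes rose and 1075 fell of 15444. Of these 2660 calls, 2621 were also made, in the same direction, by the fit of request G alone (2 ETV4AAA and 3 EYFP libraries), which called 6674 genes, 3167 up and 3507 down, so that falls prevail there, as they do with array weights (4303 up and 4530 down). The count was 4414 without replicate 1 of ETV4AAA and 1641, 1731 and 1625 without EYFP replicate 1, 2 and 3.

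Inflammatory and secreted factors were higher in ETV4AAA than in EYFP. Of 20 NF-kB inflammatory genes 15 rose and none fell (15 and 0 adjusted over the list alone), with a median change of 1.94 (adjusted p = 1.6e-11, adjusted p = 0.0428 with an estimated correlation; 2.04 within request G). Tnf rose by 3.84, Cxcl1 by 4.43 and Icam1 by 3.32. Of 28 genes of senescence and its secreted factors, 5 of which the NF-kB list also holds, 17 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 1.59 (adjusted p = 2.02e-08, adjusted p = 0.0428 with an estimated correlation; 1.45 within request G), and Ccl20 rose by 5.32. Of 31 interferon response genes 8 rose (16 up and 1 down adjusted over the list alone), with a median of 0.71 (adjusted p = 1.08e-05, adjusted p = 0.328 with an estimated correlation; 0.55 within request G), among them Cxcl9 by 4.39, Cxcl10 by 2.31 and Oas1a by 1.56. Of 18 leukocyte markers 15 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 1.96 (adjusted p = 1.47e-06, adjusted p = 0.281 with an estimated correlation; 1.36 within request G). Itgax rose by 2.88 and Itgam by 1.33, both of myeloid cells, and the B cell marker Ms4a1 fell by 2.48. The median of the leukocyte list per library was 6.43 to 7.03 in EYFP, 10.31 in replicate 1 of ETV4AAA and 7.82 and 7.75 in the others, and the cells had been sorted for an epithelial protein and EYFP.

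The lists of the cell cycle, ERK output and p53 targets were each called as higher in ETV4AAA, though some members did not pass. Of 38 cell cycle genes 25 rose (30 adjusted over the list alone) and none fell, with a median of 1.5 (adjusted p = 1.31e-12, adjusted p = 0.123 with an estimated correlation; 1.36 within request G), among them the replication helicase subunit Mcm3 by 1.97, Ccnb2 by 2.47 and Cenpa by 2.36. Of 21 genes of ERK pathway feedback and output 11 rose and none fell (11 and 0 adjusted over the list alone), with a median of 1.04 (adjusted p = 7.91e-05, adjusted p = 0.123 with an estimated correlation; 1.10 within request G), and besides Dusp6, Spry2 rose by 2.37 and Ier3 by 2.62. The list's median was 9.47 in replicate 1 of ETV4AAA and 11.33 and 11.08 in the others, against 9.52 to 10.1 in EYFP. Of 30 p53 targets 9 rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 0.54 (adjusted p = 0.000769, adjusted p = 0.0428 with an estimated correlation; 0.50 within request G). Phlda3 rose by 2.25, Tnfrsf10b by 1.72 and Plk2 by 1.39. Of 17 ETS family genes 1 rose and 2 fell (2 and 2 adjusted over the list alone), and the list was not called (median 0.11, mean -0.05, adjusted p = 0.862). Ehf and Elf5, ETS factors of epithelia, fell by 1.41 and 1.68, and Fli1 rose by 2.06.

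Lists of prostate cell types differed in direction. Of 17 distal luminal genes 2 rose and 8 fell (5 and 8 adjusted over the list alone), with a median of -1.11 (adjusted p = 0.0155, adjusted p = 0.279 with an estimated correlation and 0.184 under quantile normalization; -1.32 within request G). The secretory gene Tgm4 fell by 2.96, Mme fell by 2.43 and Apof fell by 2.14. Of 21 androgen receptor targets, 4 of which the distal luminal list also holds, 2 rose and 7 fell (3 and 9 adjusted over the list alone), with a median of -0.54 (adjusted p = 0.0155, adjusted p = 0.123 with an estimated correlation; -0.27 within request G). This list was no longer called under quantile normalization (adjusted p = 0.0952), with the request as a covariate (0.0593) or without replicate 1 of ETV4AAA (0.06). Its median level was 10.06 in replicate 1 of ETV4AAA and 10.51 and 10.63 in the others, against 10.49 to 10.63 in EYFP. Tmprss2 fell by 1.11, and the members that rose were Pmepa1 by 2.83 and Camkk2 by 1.98. Of 16 basal genes 9 rose (12 adjusted over the list alone) and none fell, with a median of 1.19 (adjusted p = 1.97e-06, adjusted p = 0.132 with an estimated correlation; 1.18 within request G), among them Krt17 by 2.23, Lamb3 by 1.53 and Itgb4 by 1.11. Of 12 proximal luminal genes 4 rose and 2 fell (4 and 2 adjusted over the list alone), and the list was not called (median 0.24, adjusted p = 0.772). Its member Ly6a rose by 4.47, Clu rose by 1.95 and Prom1 fell by 1.43. Of the 4 measured neuroendocrine genes 3 fell (3 adjusted over the list alone), Chgb by 2.81, Chga by 1.72 and Ncam1 by 0.93, with a list median of -1.32 (adjusted p = 0.0155, adjusted p = 0.123 with an estimated correlation, 0.0529 within request G and 0.423 without the filter on low values).

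Some genes of matrix and stroma rose, and their lists were called. Of 8 genes of epithelial to mesenchymal transition 6 rose (6 adjusted over the list alone), with a median of 1.74 (adjusted p = 3.19e-05, adjusted p = 0.0428 with an estimated correlation; 1.49 within request G), among them fibronectin (Fn1) by 2.17, Itga5 by 1.96 and Sparc by 1.83. Of 18 matrix proteases and regulators 6 rose (8 up and 1 down adjusted over the list alone), with a median of 1.11 (adjusted p = 0.000695, adjusted p = 0.0428 with an estimated correlation; 0.98 within request G). Plaur, the urokinase receptor, rose by 2.47, Adamts9 by 2.61 and Adam8 by 2.88. The list's median was 8.27, 7.52 and 7.24 in the ETV4AAA replicates against 6.48, 7.13 and 7.3 in EYFP, so that of replicate 3 lay within the EYFP range. Of 18 fibroblast and smooth muscle genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 1.15 (adjusted p = 0.000689, adjusted p = 0.444 with an estimated correlation; 0.85 within request G), and Rgs5 rose by 2.11, Myl9 by 1.97 and Pdgfrb by 1.38. Of 12 endothelial genes 2 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 1.41 (adjusted p = 0.00989, adjusted p = 0.279 with an estimated correlation and 0.189 with a minimum mean rlog of 5; 0.86 within request G), and Esam rose by 4.34 while Emcn fell by 1.91. The fibroblast median was 8.63 in replicate 1 of ETV4AAA and 6.62 and 6.38 in the others, against 5.49, 6.2 and 6.5 in EYFP, so that of replicate 3 lay within the EYFP range. The endothelial median was 6.91 in replicate 1 and 5.51 and 5.33 in the others, against 4.44 to 4.78 in EYFP. Of 11 Notch pathway genes 4 rose (4 adjusted over the list alone), Dtx1 by 4.67, Hey1 by 1.96 and Dll1 by 1.53 among them, with a median of 0.62 (adjusted p = 0.0336, adjusted p = 0.444 with an estimated correlation; 0.96 within request G). This call was lost with a minimum mean rlog of 5 (adjusted p = 0.139), under quantile normalization (0.0705) and without replicate 2 (0.14) or 3 (0.0902) of ETV4AAA, and the list's median level in replicate 1, 7.14, lay within the EYFP range of 6.73 to 7.23. Of 47 genes in the histone list 11 rose and 1 fell (15 and 3 adjusted over the list alone), with a median of 0.57 (adjusted p = 0.000769, adjusted p = 0.472 with an estimated correlation, and 0.06 without replicate 1 of ETV4AAA; 0.42 within request G). The median was 0.85 for its 21 H2 genes of the histocompatibility complex, such as H2-K2 at 1.83, and 0.34 for its 26 histone genes, such as Hist1h2be at 1.32.

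The lists of the unfolded protein response and of Wnt targets were called as lower. Of 19 unfolded protein response genes 1 rose and 9 fell (1 and 14 adjusted over the list alone), with a median of -0.92 (adjusted p = 5.28e-06, adjusted p = 0.123 with an estimated correlation; -0.71 within request G). Derl3 fell by 1.47, Pdia6 by 1.30 and Asns by 0.93. Of 10 Wnt targets 1 rose and 4 fell (1 and 5 adjusted over the list alone), with a median of -0.74 (adjusted p = 0.00532, adjusted p = 0.202 with an estimated correlation; -0.42 within request G), and Nkd1 fell by 2.46 and Lgr5 by 1.72. Not called were dissociation stress (4 of 24 up and 5 down, adjusted p = 0.0799), sterol and fatty acid synthesis (1 of 22 up and 1 down, adjusted p = 0.698), peripheral glia (1 of 3 up and 1 down, adjusted p = 0.897) and seminal vesicle secretion (0 of 9 up or down, adjusted p = 0.155, and 0.0152 within request G with a median of -1.52). Oxidative phosphorylation, cytosolic ribosomal proteins and mitochondrially encoded genes were not called over all libraries, with medians of 0.08, 0.25 and 0.09 (adjusted p = 0.964, 0.251 and 0.897), whereas within request G their medians were -0.26, -0.31 and -0.41 (adjusted p = 5.9e-05, 6.57e-05 and 0.00142). Of the 28 lists 19 were called, 14 up and 5 down, and 5 of them with an estimated correlation.

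**Figure D2:**
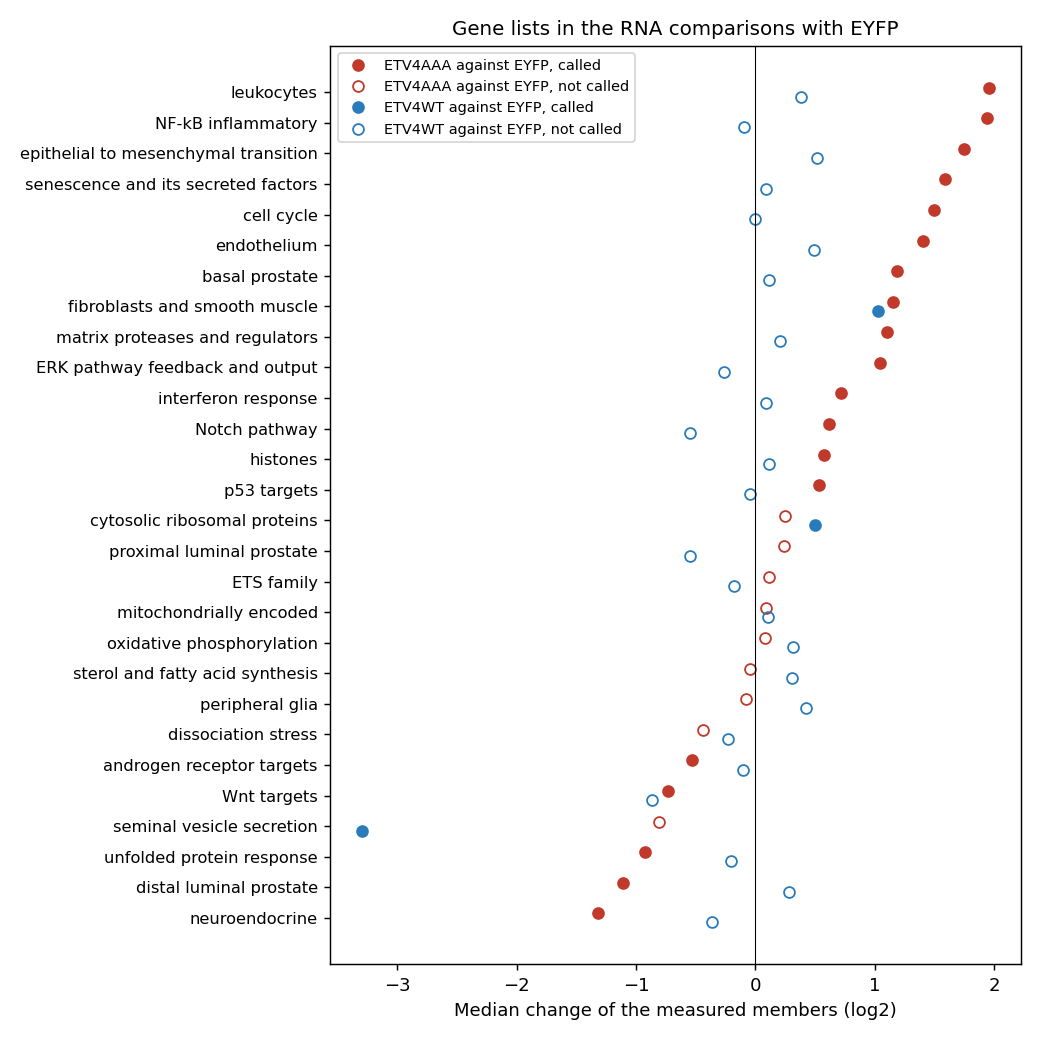
Median log2 change of the measured members of each gene list, ETV4AAA against EYFP in red and ETV4WT against EYFP in blue, filled where the list was called. The NF-kB median is 1.94 in ETV4AAA and -0.10 in ETV4WT, and the distal luminal median is -1.11 in ETV4AAA.

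**Figure D3:**
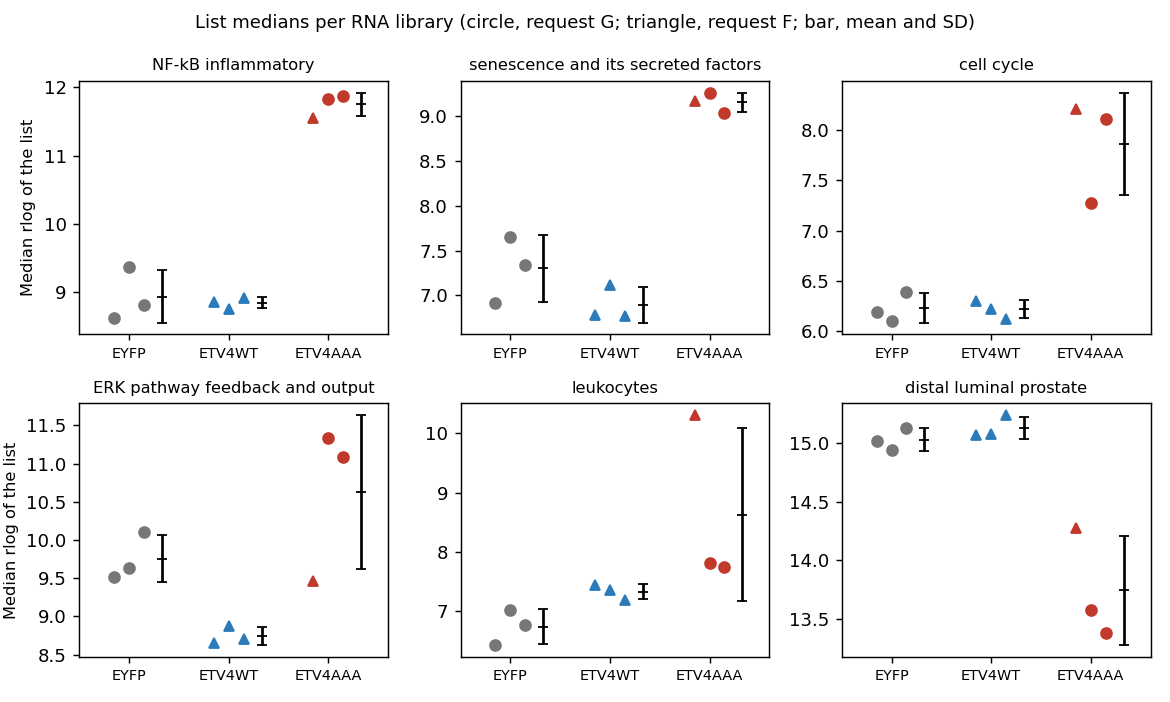
Median rlog (log2 scale) per RNA library of the NF-kB, senescence, cell cycle, ERK, leukocyte and distal luminal lists, by genotype, circles for library request G and triangles for request F. The NF-kB medians of the ETV4AAA libraries are 11.55, 11.83 and 11.87, and the leukocyte medians are 10.31 in replicate 1 and 7.82 and 7.75 in the others.

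The comparison of ETV4WT with EYFP asks the same of the wild-type form, but all ETV4WT libraries belong to request F and all EYFP libraries to request G. Tmprss2 (ENSMUSG00000000385, chromosome 16, 97564682 to 97659541), an androgen-regulated protease gene, rose from 11.05 ± 0.15 to 13.59 ± 0.16, by 2.53 (SE 0.14, adjusted p = 0.000314; 2.36 with the request as a covariate, adjusted p = 0.00158). Dusp6 rose by 1.32 (adjusted p = 0.0121; 1.60 with the covariate), a call lost without any 1 of the EYFP libraries (adjusted p up to 0.0966). It was the only member of the ERK list to rise. Of the 21 ERK genes 1 rose and 2 fell (1 and 4 adjusted over the list alone), and the list was not called (median -0.265, adjusted p = 0.386). The calcium channel gene Trpc6 rose by 2.50 (adjusted p = 0.0223; 4.20 with the covariate), and was called under 11 of 17 alternatives. Camk2b rose by 4.74 (adjusted p = 0.0274) and Svep1 by 2.46, but with the covariate these values were 0.53 (adjusted p = 0.582) and 0.02 (adjusted p = 0.976). Among the largest falls, the neurofilament gene Nefh fell by 4.77 (adjusted p = 0.019; -3.13 with the covariate, adjusted p = 0.0901), Nr2f6 by 3.85 (adjusted p = 0.021; -1.16 with the covariate) and Sox4 by 3.73 (adjusted p = 0.0241; -0.68 with the covariate, adjusted p = 0.118).

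Of 15444 genes 360 rose and 1349 fell in ETV4WT. With the request as a covariate, a fit that rests on the single ETV4AAA library of request F, 168 of these 1709 calls were made in the same direction and 262 genes had the opposite sign. The count was 19, 3 and 3 without EYFP replicate 1, 2 and 3. It was 4, 121 and 210 without ETV4WT replicate 1, 2 and 3. Without replicate 1 of ETV4AAA it was 5966, and in the fit of the compared genotypes alone 5183. Leaving out ETV4AAA libraries does not alter the ETV4WT change of any gene. Only the estimate of the spread, which all libraries share, differs in these fits. The median change of all genes was 0.11 as deposited, 0.24 under quantile normalization, where 785 genes rose and 1128 fell, and 0.41 after centring on medians, where 2237 rose and 1365 fell, so which direction prevails depends on the scaling.

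Few lists were called in ETV4WT. Of 18 fibroblast and smooth muscle genes 5 rose (6 adjusted over the list alone), with a median of 1.03 (adjusted p = 0.000618, adjusted p = 0.868 with an estimated correlation; -0.27 with the covariate, adjusted p = 0.693), among them the collagen genes Col1a2 by 1.81, Col6a1 by 1.68 and Col3a1 by 1.68. Seminal vesicle secretion genes were lower, with a median of -3.30 (adjusted p = 0.000618, adjusted p = 0.868 with an estimated correlation; -5.07 with the covariate, adjusted p = 0.0862 with array weights). None of its 9 members passed over all genes and 9 fell adjusted over the list alone, and Svs2 was at -3.52 (adjusted p = 0.0502). The list's median per library was 11.04, 13.32 and 10.21 in ETV4WT, against 13.24, 15.77 and 15.92 in EYFP. That of ETV4WT replicate 2 thus lay within the EYFP range. Cytosolic ribosomal protein genes were higher, with a median of 0.50 (adjusted p = 0.000618, adjusted p = 0.92 with an estimated correlation), but lower with the covariate (-1.15, adjusted p = 7.25e-17). Of its 78 members 2 rose (1 adjusted over the list alone), Rpl9 by 1.65 and Rpl10 by 0.95. The other lists were not called, with adjusted p from 0.0763 (Notch pathway) to 0.894 (senescence), where the median was 0.09 and the mean -0.25. No NF-kB gene and no cell cycle gene passed in this fit, whose spread also takes in the ETV4AAA libraries. Of 30 p53 targets 4 fell (2 up and 5 down adjusted over the list alone), among them Plk3 by 3.23, Phlda3 by 1.63 and Bbc3 by 1.24, with a list median of -0.05 (adjusted p = 0.569).

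**Figure D4:**
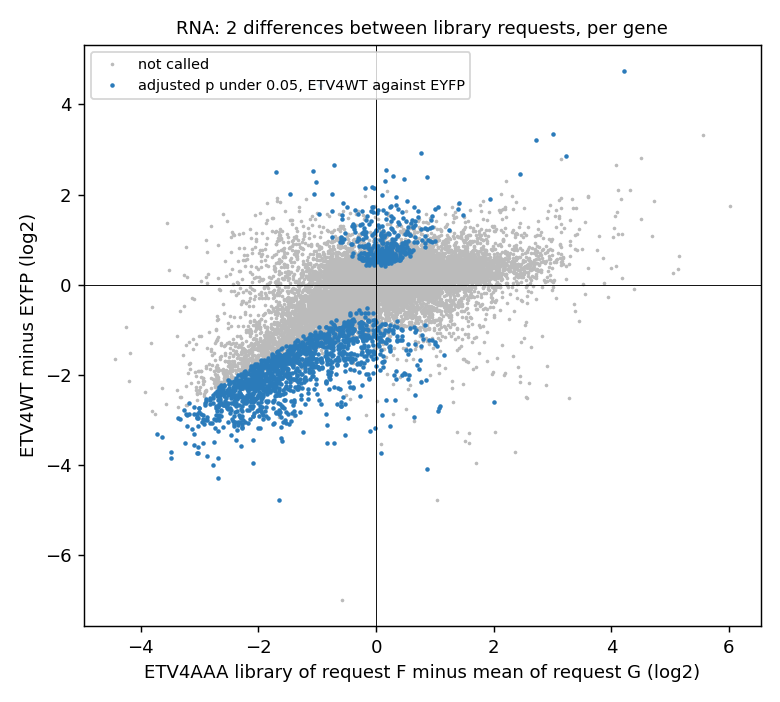
Log2 change per gene in ETV4WT against EYFP (y axis) over the ETV4AAA library of request F minus the mean of the ETV4AAA libraries of request G (x axis), blue where called in ETV4WT. The 1349 genes that fell in ETV4WT have a median of -1.49 on the x axis.

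The direct comparison of ETV4AAA with ETV4WT tests whether the forms differ. Bcan, a proteoglycan gene, was higher in ETV4AAA by 8.00, Pyy by 7.87 (SE 0.56, adjusted p = 4.42e-05; 9.24 within request F), Flt4 by 7.46 (adjusted p = 1.66e-05; 8.16 within request F) and the intermediate filament gene Nes by 6.36 (SE 0.31, adjusted p = 9.03e-06; 5.94 within request F). Tmprss2 was lower by 3.64 (SE 0.14, adjusted p = 3.82e-06), where the value within request F was -3.52. Its mean was 11.05 in EYFP, 13.59 in ETV4WT and 9.95 in ETV4AAA, so the larger part of this difference is its rise in ETV4WT. Whether the alleles the mice carry bear on it was not tested. C1s2 was lower, at -4.08 and at -4.29 within request F. Trp53 was higher by 1.11 (adjusted p = 0.00658; 1.62 within request F). The secretory gene Tgm4 was at -3.49, and Dsc1, Gprc6a, C1rb, Cckar, Ren1, Mt3 and Tcaf3 were at -3.73 to -3.31. Of 15444 genes 2486 were higher and 1982 lower. Of these 4468 calls 2045 were also made within request F (1 against 3 libraries), the count was 2825 without replicate 3 of ETV4AAA and 8544 without its replicate 1, and the direction that prevails turned under quantile normalization (1859 higher, 2986 lower; median of all genes -0.14) and centring (1761 and 3588; median -0.25).

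Of the 28 lists 16 were called in this comparison, 12 up and 4 down, and 0 with an estimated correlation, where the p nearest to the threshold were 0.0774 for senescence, 0.0933 for p53 targets and 0.0999 for NF-kB. Of 20 NF-kB genes 15 were higher in ETV4AAA (17 adjusted over the list alone) and none lower, with a median of 2.72 (adjusted p = 7.89e-09; 2.13 within request F). Of 28 senescence genes 19 were higher and 2 lower (22 and 2 adjusted over the list alone; median 1.88, adjusted p = 1.42e-07; 1.77 within request F), and of 38 cell cycle genes 28 were higher and 1 lower (29 and 1 adjusted over the list alone; median 1.69, adjusted p = 7.89e-09, adjusted p = 0.239 with an estimated correlation; 1.56 within request F). Of 21 ERK genes 13 were higher (14 up and 1 down adjusted over the list alone), Dusp6 by 3.22, Lif by 3.13 and Epha2 by 3.04 among them, with a median of 1.88 (adjusted p = 6.85e-06, adjusted p = 0.119 with an estimated correlation; 1.43 within request F). Of 30 p53 targets 9 were higher and 2 lower (13 and 2 adjusted over the list alone; median 0.71, adjusted p = 0.00123; 0.47 within request F), with Phlda3 at 3.87 and Bbc3 at 1.83. Basal genes were higher with a median of 1.20 (adjusted p = 0.000172, adjusted p = 0.298 with an estimated correlation), and of 1.11 within request F. Leukocyte markers were higher with a median of 1.60 (adjusted p = 0.000851, adjusted p = 0.492 with an estimated correlation), and of 2.84 within request F. The leukocyte level was 10.31 in replicate 1 of ETV4AAA, its only library of request F, and 7.82 and 7.75 in the others. In ETV4WT it was 7.19 to 7.44. Distal luminal genes were lower, with a median of -1.23 (adjusted p = 0.00708, adjusted p = 0.298 with an estimated correlation and 0.215 under quantile normalization; -0.24 within request F).

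Among the remaining calls of this comparison, Notch pathway genes were higher, with a median of 1.67 (adjusted p = 0.00289, adjusted p = 0.347 with an estimated correlation, and 0.0669 within request F with a median of 0.89). Without replicate 1 of ETV4AAA the calls ended for interferon response (median 0.73, adjusted p = 0.00359, then 0.198), epithelial to mesenchymal transition (1.08, 0.00708, then 0.0558), proteases (0.93, 0.00909, then 0.098), histones (0.84, 0.0159, then 0.477), unfolded protein response (-0.58, 0.00123, then 0.0501) and sterol and fatty acid synthesis (-0.28, 0.0347, then 0.098). With an estimated correlation their adjusted p were 0.572, 0.143, 0.119, 0.602, 0.306 and 0.492. Cytosolic ribosomal proteins had a median of -0.23 (adjusted p = 0.0292, adjusted p = 0.754 with an estimated correlation) and of 0.92 within request F (adjusted p = 1.31e-06), and their call was also lost after centring (adjusted p = 0.0629) and without ETV4WT replicate 3 (0.158) or replicate 2 (0.609) or 3 (0.333) of ETV4AAA.

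Chromatin accessibility differed at many regions between ETV4AAA and EYFP, in bulk libraries of sorted cells whose purity is not known here. Whether the regions changed within cells or the mix of cells differed was not tested. Of 181278 regions 45463 (25.1%) opened, with a median change of 1.35, and 47080 (26%) closed, with a median of -1.38, and changes of at least 1 in absolute size made up 31778 and 34496 of these. Opened regions had a median level of 4.21 in EYFP and 5.75 in ETV4AAA, and closed regions had 5.25 and 3.68. A region on chromosome 7 (mm9, 20052011 to 20052512) was at 2.20 and 1.35 in the EYFP libraries, at 1.33 and 1.63 in ETV4WT and at 8.06 and 8.35 in ETV4AAA (adjusted p = 6.09e-09), where 3 reads correspond to 2.20 and 2.50 in EYFP and 1.71 and 1.63 in ETV4WT. A region on chromosome 14 (51618028 to 51618468) had no reads in EYFP and was at 6.57 and 6.66 in ETV4AAA. A region on chromosome 6 (126325053 to 126325743) was at 7.46 and 7.37 in EYFP, at 2.26 and 2.87 in ETV4WT and at 0 and 2.53 in ETV4AAA (adjusted p = 3.24e-07), where 3 reads correspond to 2.02 and 1.95. A region on chromosome 7 (70947543 to 70948109) was at 6.92 and 6.62 in EYFP, at 7.45 and 7.63 in ETV4WT and at 2.61 and 0 in ETV4AAA. Genes at these regions were not analysed here.

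Fewer regions differed between ETV4WT and EYFP. Of 181278 regions 14920 (8.2%) opened, with a median change of 0.90, and 22673 (12.5%) closed, with a median of -1.52. The region on chromosome 14 from 121883339 to 121884481 was at 4.34 and 3.36 in EYFP, 7.60 and 7.65 in ETV4WT and 5.78 and 5.36 in ETV4AAA, a rise of 3.78 (SE 0.28, adjusted p = 2.46e-07) in ETV4WT. Another on that chromosome (121342052 to 121342616) was at 2.54 and 3.13 in EYFP, 6.15 and 6.18 in ETV4WT and 4.94 and 5.07 in ETV4AAA, a rise of 3.33 (SE 0.31, adjusted p = 1.48e-06). The region on chromosome 7 from 73422809 to 73423243 was at 5.58 and 5.90 in EYFP, had no reads in ETV4WT and was at 3.73 and 4.33 in ETV4AAA. The number of changed regions fell from 37593 to 24126 without EYFP replicate 1 and to 14826 and 18640 without ETV4WT replicate 1 and 2, and it was 22296 after thinning all libraries to 7495561 reads. Opened regions numbered 3054 and 4243 without ETV4WT replicate 1 and 2, where closed regions numbered 11772 and 14397. There were 4772 opened and 15139 closed regions without a variance trend, and 7241 and 15055 after thinning. Without EYFP replicate 1 there were 9634 opened and 14492 closed regions.

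Between the ETV4 genotypes 45697 regions (25.2%) were more open in ETV4AAA, by a median of 1.49, and 43909 (24.2%) were less open, with a median of -1.41. Which direction prevails depends on the processing. Less open regions prevailed under quantile normalization (40647 more open, 46345 less open), centring (42096 and 47402) and thinning (34204 and 39585). They also did without the regions of lowest mean (32612 and 34263) and without either ETV4AAA library, but not in the other alternatives. On chromosome 4, the region from 144956955 to 144957689 was at 2.81 and 3.36 in EYFP, 2.01 and 1.63 in ETV4WT and 8.02 and 8.57 in ETV4AAA (adjusted p = 5.75e-10). On chromosome 10, the region from 8703033 to 8703796 was at 6.83 and 7.67 in EYFP, 8.38 and 8.14 in ETV4WT and 3.03 and 3.53 in ETV4AAA, a fall of 4.99 (SE 0.25, adjusted p = 3.45e-10). The ATAC libraries carry 1 request, so this batch does not bear on them.

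**Figure D5:**
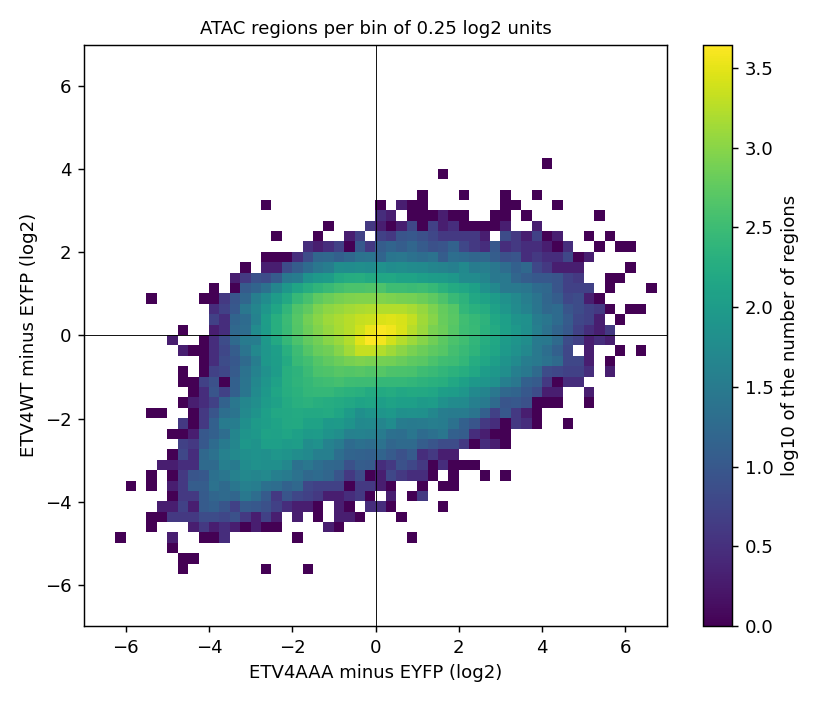
Number of regions (log10 colour scale) by log2 change in ETV4AAA against EYFP and in ETV4WT against EYFP, in bins of 0.25. The correlation across regions is 0.279, and 12317 regions closed in both comparisons.

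The responses to the ETV4 forms were set side by side, with the caveat that both use the same EYFP libraries. Across genes the changes correlated with r = 0.339, and across regions with r = 0.279, where genes and regions are not independent replicates. Unchanged groups simulated against the same controls gave r = 0.5 and 0.498. These are the values for noise alone, and real changes alter r, so they are no benchmark for the observed r. The covariances were 0.279 for RNA and 0.301 for ATAC, against 0.078 and 0.071 in the simulation, an excess of 0.201 and 0.229. Noise in the shared controls thus gives only part of them. Whether the library request adds to the covariance in RNA was not tested. In RNA 96 genes rose and 108 fell in both, where independent calls would give 36.9 and 93.9, and 21 rose in ETV4AAA and fell in ETV4WT while 38 did the opposite. In ATAC 5442 regions opened and 12317 closed in both, where independent calls would give 3741.8 and 5888.4. There, 3292 opened in ETV4AAA and closed in ETV4WT, while 3696 did the opposite. Calls against the same EYFP libraries are not independent, so these figures for genes and regions do not test a shared response. The EYFP libraries, 3 and 2 in number, cannot be divided into groups of at least 2 to give each comparison its own controls. In RNA, r was 0.228 with the request as a covariate. It was 0.111 without replicate 1 of ETV4AAA, the only ETV4AAA library that shares request F with ETV4WT. A part of the RNA correlation thus rests on that library, and its request and its own biology cannot be told apart.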

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

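The voom and thinned ATAC fits were added after seeing the data; the other alternatives were chosen before. Counts of changed genes, their split by direction and the list calls depend on the processing. Of the 2660 genes called in ETV4AAA against EYFP, 1616, 1692 and 1592 were kept without EYFP replicate 1, 2 and 3, and of the 4468 in ETV4AAA against ETV4WT, 2045 were kept within request F and 2588 with only the compared genotypes. Genes taken by the naming rule, some of which the text leaves out, were chosen for large changes or small p. Over all alternatives, those of ETV4AAA against EYFP gave the same verdict in 1721 values, gained a call in 32 and lost one in 92. For ETV4AAA against ETV4WT these values were 1728, 21 and 81. The same verdict includes genes called in neither fit. For ETV4WT against EYFP the verdict was the same in 1244 values, a call was gained in 122, lost in 367 and the direction reversed in 6. Without EYFP replicate 1, 2 and 3, 51, 52 and 52 of these genes lost a call, and 52, 51 and 51 kept the verdict. Without ETV4WT replicate 1, 2 and 3, 51, 46 and 43 lost a call, and 52, 55 and 60 kept the verdict. The verdicts on named regions were the same in all 134, 132 and 137 values of ETV4AAA against EYFP, ETV4WT against EYFP and ETV4AAA against ETV4WT. These regions were picked for large changes without overlap. In the fits without the regions of lowest mean, only 4, 2 and 7 of them remained to be counted. Unless the construction shows it (fewer libraries, a stricter minimum), the cause was not tested.

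Genes changed in ETV4AAA against EYFP, 2660 as reported, numbered 8833 with array weights, 4416 with the request as a covariate, 6674 within request G, and 1625 to 4414 leaving out 1 library (1641, 1731 and 1625 without EYFP replicate 1, 2 and 3, and 4414 without ETV4AAA replicate 1). In ETV4WT against EYFP the 1709 became 651 without a filter, 3602 after median centring, 5845 with array weights, 5183 with only the compared genotypes, and 3 to 5966 leaving out 1 library: 19, 3 and 3 without EYFP replicate 1, 2 and 3, 4, 121 and 210 without ETV4WT replicate 1, 2 and 3, and 5966 without ETV4AAA replicate 1. With the covariate there were 1734 (459 up, 1275 down), of which 168 are among the 1709. In ETV4AAA against ETV4WT the 4468 became 2974 at an absolute change of at least 1, 10391 with array weights, 2615 with only the compared genotypes, and 2825 (without ETV4AAA replicate 3) to 8544 (without replicate 1). The estimation of array weights gave convergence warnings. In ETV4WT against EYFP, leaving out ETV4AAA replicate 1 or all ETV4AAA libraries left every change as it was. Only the estimate of the spread differed there. For the other counts the cause was not tested.

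Lists called went from 19 to 5 with an estimated correlation in ETV4AAA against EYFP (19 to 21 leaving out 1 library) and from 16 to 0 in ETV4AAA against ETV4WT (12 to 17). In ETV4WT against EYFP the 3 became 0 with an estimated correlation, 6 without a filter, 5 with only the compared genotypes, 8 with the covariate, all down, and 3 to 5 leaving out 1 library (5 without ETV4WT replicate 3 or ETV4AAA replicate 1). The cause was not tested.

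Reversed list medians of oxidative phosphorylation, cytosolic ribosomal proteins and mitochondrially encoded genes in ETV4AAA against EYFP were -0.202, -0.261 and -0.365 with array weights, and -0.257, -0.312 and -0.414 with the covariate, within request G, and without ETV4AAA replicate 1. Leaving out 1 library their ranges were -0.257 to 0.233, -0.312 to 0.569 and -0.414 to 0.347, the upper ends without ETV4AAA replicate 2. In ETV4WT against EYFP the covariate reversed the interferon response (-0.592), oxidative phosphorylation (-0.7), leukocytes (-1.396), fibroblasts and smooth muscle (-0.268), cytosolic ribosomal proteins (-1.148), mitochondrially encoded genes (-0.895) and histones (-0.83), and the genes Igfbp7 (0.24), Dusp5 (0.105), Ets2 (0.052), Edem1 (0.163), Nkd1 (0.075) and mt-Rnr1 (-1.675). In ETV4AAA against ETV4WT the covariate and request F alone gave 0.448 for oxidative phosphorylation, 0.891 for fibroblasts and smooth muscle, 0.92 for cytosolic ribosomal proteins and 0.591 for mitochondrially encoded genes. The cause was not tested.

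Across genes, r between the responses, 0.339 as reported, was 0.111 with array weights, 0.228 with the covariate and 0.111 to 0.427 leaving out 1 library (0.111 without ETV4AAA replicate 1). Across regions, 0.279 became 0.205 without the 45320 regions of lowest mean, 0.334 under quantile normalization and 0.26 to 0.333 leaving out 1 library. Regions changed in ETV4WT against EYFP, 37593, became 22802 at an absolute change of at least 1, 19911 without a variance trend, 22296 after thinning and 14826 to 41246 leaving out 1 library (24126 without EYFP replicate 1, and 14826 and 18640 without ETV4WT replicate 1 and 2). For ETV4AAA against EYFP the range leaving out 1 library was 72857 to 85402, and for ETV4AAA against ETV4WT 62495 to 93832. With the replicate number as a block the counts were 93577, 39679 and 90626, although deviations of libraries sharing a number correlated at 0.061 at most, so the numbers are not read as pairs. A library left alone in its genotype is assumed to vary like the others. The RNA depth is unknown, and 3 reads in ATAC stand at 1.63 to 2.50. Motifs and genes next to regions, with their alternatives, were not run. The cause was not tested.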

Other observations

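The fits within request G and with the request as a covariate were planned before the data were examined. Their use as tests of explanations, and the other tests in this part, were chosen after the results were seen.

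The windows given here were picked as extremes of their median change, with no test of them. Over 2085 windows of 1000000 bases with at least 20 regions (mm9), the window on chromosome 13 from 61000001 to 62000000 had the highest median change in ETV4AAA against EYFP, 1.89, with 78.1% of its 32 regions opened and library medians of 3.32 and 3.46 in EYFP and 5.35 and 5.39 in ETV4AAA. On chromosome 14, the window from 50000001 to 51000000 had a median of 1.55, with 76.2% of its 21 regions opened, and its median in ETV4WT was 0.01. The window on chromosome 19 from 28000001 to 29000000 had the lowest median in ETV4AAA, -1.65, with 63.4% of its 41 regions closed and 14.6% opened, and in ETV4WT it was at -1.33, with 56.1% closed. The window on chromosome 2 from 16000001 to 17000000 was at -1.35 and -1.40 in ETV4AAA and ETV4WT. Both genotypes are compared with the same EYFP libraries. Of the regions on chromosome 13, 31.5% closed and 22% opened in ETV4AAA, and of those on chromosome X, 21.3% closed and 27.3% opened.

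Genes that differed between ETV4WT and EYFP were set against the difference between library requests. Over the 1349 genes that fell in ETV4WT, with a median of -1.88, the ETV4AAA library of request F lay below the mean of those of request G by a median of -1.49 (interquartile range -2.05 to -0.74), and 92.9% of them had this direction, against 69% of the genes not called whose ETV4WT change was also negative. A difference between requests may therefore account for many of these falls, though it rests on 1 ETV4AAA library, whose own biology is an open alternative. Over the 360 genes that rose, with a median of 0.86, the same difference was 0.14, and 67.2% had the direction of the rise against 67.6% of the genes not called whose ETV4WT change was also positive, which leaves the request and the genotype unable to be told apart for them. Across all genes the difference between the requests correlated with the ETV4WT change at r = 0.599, where genes are not independent replicates.

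The rise of NF-kB genes in ETV4AAA was weighed against the request and against RNA from leukocytes. Within request G its median change was 2.04, so a difference between requests cannot be the whole cause. Leukocyte markers that rose lay below the NF-kB genes that rose by -3.4 and -3.56 in replicates 2 and 3 of ETV4AAA, but by -1.17 in replicate 1, where the 95% interval over members, -2.24 to 0.94, includes 0, and the most abundant of these markers, Cd74 and Lyz2, reached 13.79 and 12.61 there. Levels of different genes do not show which cells the NF-kB RNA came from, so this comparison cannot decide. RNA of leukocytes stays open as a source. The cells were sorted as positive for both EpCAM and EYFP, but the purity of the sort is not known here. Of the leukocyte markers, 2, H2-Aa and H2-Ab1, also stand in the histone list. An effect of the altered ETV4 form on the epithelial cells is the other explanation the design names, and no test told them apart.

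Tmprss2 was higher and CreERT2 lower in ETV4WT than in EYFP. With the request as a covariate the Tmprss2 change was 2.36, which speaks against the request as its whole cause, but this estimate rests on 1 ETV4AAA library of request F and leaves the request open. Fewer copies of the CreERT2 allele in ETV4WT could give the CreERT2 change of -0.62. This cannot be told apart from lower transcription, since the labels give no copy number. Tmprss2 minus CreERT2 was -2.09, -2.04 and -2.25 in the EYFP libraries and 1.36, 0.84 and 0.87 in those of ETV4WT. In those of ETV4AAA it was -1.44, -1.76 and -1.75, so ETV4WT departed further from EYFP than ETV4AAA did. Whether the copies of this allele also bear on Tmprss2 was not tested. An allele difference and an effect of ETV4 on Tmprss2 both stay open and cannot be told apart here.

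With 3 libraries per genotype there are 10 splits, too few for a share under 0.05. Every other split mixes both genotypes within its groups. This puts most of a genotype difference into the spread and keeps part of it between the groups. Counts of the other splits therefore do not show what unchanged libraries would give, for genes or for lists. In ETV4WT against EYFP the real split is also that of request F against request G. The real split gave the most changed genes, as 1 of 10, in ETV4AAA against EYFP (2660, against 0 at most in the other splits), in ETV4WT against EYFP (1709, against 0) and in ETV4AAA against ETV4WT (4468, against 1). For list calls the real split gave 19 and the highest other 18 in ETV4AAA against EYFP, so only 1 split, the real one, gave as many. In ETV4WT against EYFP it gave 3 and the highest other 10, and all 10 splits gave as many as the real one. In ETV4AAA against ETV4WT it gave 16 and the highest other 17, and 3 splits, the real one included, gave as many.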
